A study of Mus musculus with 2 samples.

How the data were processed

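The series holds DNase-seq of the left cerebral cortex of 2 male mice aged 36 days, 1 library per mouse. For each library the authors gave 2 peak lists, a list of false discovery rates of the cut rate, and a list of footprints, all on mm10 (GRCm38) and, per the deposited file list, made from the filtered alignments of that library without pooling the mice. The peak caller, the aligner, their versions and thresholds are not given in the sources used here. The deposited peak lists give a signal per peak, its height, whose normalization is not stated. Values were whole multiples of 1 step in each library (100% within 0.02 of a step), and the authors' file list names a depth-normalized signal track. The heights were therefore read as cuts scaled to library depth, and that depth, 160.1 and 145.4 M cuts, is inferred from the steps. Comparison of heights between the mice rests on that reading. The deposited false discovery rate list gives an adjusted p-value (q-value) per run of bases, and only bases at or under 0.05 were listed, 44.5 Mb in replicate 1 and 29.5 Mb in replicate 2. The other deposited value, the score of a footprint, was 0.01 throughout and was not used. Footprint positions were used. Read data and signal tracks were not used here.

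Of the 2 peak lists, every peak of 1 list overlapped bases at a rate of 0.001 or less, and this list was the main one. The longer list (125119 and 103840 peaks) overlapped bases at 0.05 or less, except for 1 peak of replicate 1. Chromosomes 1 to 19 and X were used, and Y was kept apart. Genes and start sites came from GENCODE M21, and sequence from GRCm38.p6. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with matplotlib 3.10.9 for the figures. Coordinates are 1-based with both ends included.

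A peak was shared if at least 1 bp overlapped a peak of the other mouse. Sites are peaks of both mice merged where they overlap, 82968 in all, of which 43755 were in both, 25656 in replicate 1 alone and 13557 in replicate 2 alone. Positions were shuffled 100 times within chromosomes. A peak was a promoter peak if its midpoint lay within 1 kb of a start site, and otherwise exon, intron or intergenic. The promoter value of a gene is its highest peak that comes within 1 kb of any of its annotated start sites, with 0 where no peak was listed, and a list gives no value under its threshold. Such a peak need not lie at the start site, and some lay in introns, as at Ckm and Apob. Each list's share and its median number of peaks were placed among 10000 random lists of the same size matched on CpG content of the promoter and on gene length. All 287 genes of the 22 lists were found in the annotation. Sequence patterns, 24 in all, were searched on both strands in peaks, in footprints and in flanks 1 kb away, beside the reversed but not complemented pattern, with exact Poisson intervals. Footprint matches are those inside a footprint over at least 50% of their length. GC content of sites was taken over 500 bp around each site. List ratios were compared with promoters of like GC content and height, 12532 of which had a peak in both mice. For promoters, GC content was taken over 1 kb around the annotated start of the gene. That need not be the start site with the highest peak.

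The gene lists, patterns, comparisons, alternatives and the rule for naming genes were set before the data were examined. Exceptions are named below where they were added or chosen after the data were seen. The rule named, per list, the 3 genes with the highest mean promoter height and the 2 with the lowest, in alphabetical order on ties, and each gene with a promoter peak in 1 mouse alone. It also named the 10 highest peaks, the 10 genes with the most shared sites and the 5 peaks with the largest ratio in each direction. Where fewer than 3 genes of a list had a peak, the ties at 0 are given as genes without a peak. Not every gene that the rule takes is named in the text. Olfactory and vomeronasal receptor genes were taken as whole families. The other families in the closing section and the promoters shown with their sequence matches were chosen after their values were seen. Alternatives were the longer peak list, the higher 50% of the peaks by height, equal numbers of peaks, reciprocal overlap, other promoter windows, coding genes alone, random lists matched on length alone, the gene body alone, distal or shared peaks, footprint overlap by 1 bp, no scaling, absence from both lists and leaving out each mouse.

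The procedures were tested on simulated data. A planted sharing of 60.0% was recovered as 61.4%, 500 of 500 planted patterns were found, and a GC slope of 0.04 came back as 0.0403. A planted list shift of 1 was recovered as 1.11, and of 30 lists without a shift 0 in the share test and 2 in the ratio test fell outside the central 95% of random lists. With 1 group and 1 library per animal there is no test across animals and no p. Errors are the SD over 2 mice. Wilson and Poisson intervals cover counting error alone, and peaks, sites and genes are not independent replicates.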

Results

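DNase-seq maps open chromatin as the places where the enzyme DNase I cuts DNA in isolated nuclei. It was measured in the left cerebral cortex of 2 male B6CASTF1/J mice aged 36 days, 1 library per mouse, named replicate 1 and replicate 2 in the labels. Both mice belong to 1 group. They carry the same donor label but are numbered as separate males. The values give a map of accessible sites in this tissue and a comparison of the 2 mice, without any test between groups. Peak heights were read as cut counts scaled to library depth, which puts the libraries at 160.1 M cuts for replicate 1 and 145.4 M for replicate 2. On chromosomes 1 to 19 and X there were 72021 peaks in replicate 1 and 59150 in replicate 2 (65585.5 ± 9101, SD, n = 2 mice), with a median width of 202.5 ± 3.54 bp. They covered 16.0 and 11.2 Mb of GRCm38, or 0.626% and 0.439% of the sequenced bases. The longer of the authors' peak lists held 125119 and 103840 peaks. The median height was 1.18 in replicate 1 and 0.963 in replicate 2. If heights are such counts, the median height stands for 189 and 140 cuts, with a counting error of 7.27% and 8.45%.

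Nearly all promoters of cortical excitatory neuron genes and of neuronal and synaptic genes had a peak in both mice. Of 16 cortical excitatory neuron genes, 16 in replicate 1 and 15 in replicate 2 had a peak within 1 kb of an annotated transcription start site (96.9% ± 4.42, SD, n = 2), beside 74.4% and 67.5% for random lists matched on promoter CpG content and gene length. The highest promoter in this list was that of Tle4, a transcriptional corepressor of deep-layer neurons, at 14.4 ± 1.80 (mean height ± SD, n = 2, here and below). Camk2a, a subunit of the synaptic kinase CaMKII, had 4.08 ± 1.19, and Nrgn, the postsynaptic calmodulin-binding protein neurogranin, had 3.84 ± 1.37. Fezf2, a transcription factor of subcortical projection neurons, had the lowest value, 1.39 in replicate 1 with no peak in replicate 2, and Foxp2 had 1.17 ± 0.415. All 15 neuronal and synaptic genes had a promoter peak in both mice, led by the synaptic calcium sensor Syt1 at 5.05 ± 0.743, the neuronal tubulin Tubb3 at 4.35 ± 1.55 and the AMPA receptor subunit Gria2 at 4.14 ± 1.30. Gria1, another AMPA receptor subunit, had the lowest value in that list, 1.54 ± 0.274. The Camk2a peak lay on chromosome 18 at 60925441 to 60925700 in replicate 1 and at 60925481 to 60925680 in replicate 2. The Tle4 peak lay on chromosome 19 at 14598241 to 14598580 and at 14598241 to 14598500. Among 10000 matched random lists, the excitatory list stood at percentile 99.995 in replicate 1 and 99.91 in replicate 2, and the neuronal and synaptic list at 99.2 and 99.8. By median number of peaks in the gene body and 10 kb on each side, replicate 2 stood lower. Excitatory genes had 10.5 and 4 (percentiles 100 and 75.9), and neuronal and synaptic genes 6 and 4 (96.5 and 79.15).

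Genes of cortical inhibitory neurons had lower promoter peaks and differed between the mice. A peak was present at 12 of 16 promoters in replicate 1 and at 6 of 16 in replicate 2 (56.2% ± 26.5), at percentiles 46.2 and 0.175. Against lists matched on gene length alone, replicate 2 stood at 7.05, inside the central 95%. The highest were Adarb2 at 1.66 ± 0.535 and the homeobox gene Dlx6 at 1.29 ± 0.570. The neuropeptide genes Sst and Vip had no promoter peak in either mouse. In replicate 1 alone, peaks were called at Gad1 (1.22) and Gad2 (0.831), which encode the enzymes of GABA synthesis, and at Pvalb (1.22), Npy (1.11), Dlx5 (1.09), Dlx2 (0.987), Nxph1 (0.856) and Lhx6 (0.806). In replicate 2 alone, peaks were called at Slc32a1, the vesicular GABA transporter (1.07), and at Dlx1 (1.01).

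Glial promoters were accessible in part. Astrocyte genes had a promoter peak at 12 of 14 in replicate 1 and 8 of 14 in replicate 2 (71.4% ± 20.2), at percentiles 98.8 and 51.9, the first of which was 96.0 against lists matched on gene length alone. Glul, the glutamine synthetase of astrocytes, had a height of 4.58 ± 0.493, and the transcription factor Sox9 had 2.32 ± 0.171. The glutamate transporter Slc1a2 had 2.28 ± 0.983, with the highest peak of each mouse at a different place near its start sites. Fgfr3 (1.17), Aldh1l1 (1.09) and Slc1a3 (0.918) were among those with a peak in replicate 1 alone, and the water channel gene Aqp4 and the gap junction gene Gja1 had none. Oligodendrocyte genes had peaks at 6 and 7 of 14 promoters (46.4% ± 5.05), at percentiles 3.86 and 33.5. Among them, Mbp, which encodes a major myelin protein, had 1.98 ± 1.00 from different start sites in the 2 mice, the transcription factor Olig1 had 1.90 ± 0.0186 and Myrf had 1.34 ± 0.941. Nkx6-2 had a peak in replicate 1 alone (0.700), Mog (0.7498) and Cldn11 (0.667) in replicate 2 alone, and Mag and Ermn in neither. Oligodendrocyte precursor genes had peaks at 5 of 8 promoters in each mouse, at percentiles 30.3 and 49.8. Pdgfra, the growth factor receptor of these cells, had 1.57 ± 0.471, Vcan 1.52 ± 0.0348 and Ptprz1 1.19 ± 0.849. The Pdgfra peak lay 462 and 442 bp downstream of the nearest start site and held a CTCF match. C1ql1 had a peak in replicate 1 alone (1.76) and Gpr17 in replicate 2 alone (0.784), while Cspg4 and Neu4 had none.

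Microglial and vascular genes had few promoter peaks. Of 15 microglial genes, 5 in replicate 1 and 3 in replicate 2 had one (26.7% ± 9.43), at percentiles 31.1 and 7.33, or 1.62 and 0.24 against lists matched on gene length alone. Among them, the transcription factor Sall1 had 1.496 ± 0.949 and Aif1 1.22 ± 0.412. C1qc (1.53) and Trem2 (1.04) had a peak in replicate 1 alone, and the complement genes C1qa and C1qb had none. Of 13 endothelial and mural cell genes, 5 and 2 had a promoter peak (26.9% ± 16.3), at percentiles 0.335 and 0.005. Slc2a1, the glucose transporter of brain capillaries, had 3.49 ± 1.89 from different places near its start sites, and the pericyte gene Rgs5 had 0.631 ± 0.299. Kdr (0.725), Kcnj8 (0.593) and Abcb1a (0.568) had a peak in replicate 1 alone, and the endothelial junction genes Cdh5 and Cldn5 had none. Of 5 meningeal fibroblast genes, 1 had a promoter peak, Col1a1 at 1.87 ± 0.321, while Col1a2 and Col3a1 had none. The Col1a1 peak lay in an intron, at -525 and -495 bp from the nearest start site, and held a CTCF match. That list stood at percentiles 35.1 and 42.3. By length alone replicate 1 lay below the central 95% of random lists, and replicate 2, at 3.34, inside it.

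Over the 8 lists of cortical cell types, 76 of 111 promoters in replicate 1 and 61 of 111 in replicate 2 had a peak (61.7% ± 9.56), beside 63.5% and 58.4% of all 21728 protein-coding genes. Over the 5 lists of other tissues and the germ line, 12 and 9 of 64 had one (16.4% ± 3.31). The percent of genes of other tissues and germ line with a promoter peak was 26.6 within 2500 bp of a start site and 7.81 with the higher 50% of the peaks. Promoter peaks follow CpG content as well as cell type, so a list without a peak in bulk tissue is not shown to be closed in every cell. For olfactory receptor genes the counts were 12 and 11 of 1134, and for vomeronasal receptor genes 2 and 1 of 330, families with many near-copies that are hard to map.

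Genes switched on by neuronal activity and genes of the circadian clock had some of the highest promoter peaks of the fixed lists. All 16 activity-regulated genes had a peak in both mice, at percentiles 96.6 and 99.1 (99.995 and 100 by length alone), with the postsynaptic scaffold gene Homer1 at 7.68 ± 3.20, the transcription factor Egr1 at 7.51 ± 2.79 and the synaptic gene Arc at 6.95 ± 3.32. The highest Egr1 and Bdnf peaks of the 2 mice were at different places near their start sites. The lowest in the list were Npas4 at 2.76 ± 1.68 and Bdnf at 1.64 ± 0.744. All 12 clock genes had a peak in both mice, at percentiles 78.7 and 90.8, or 99.7 and 99.95 by length alone. The period gene Per1 had 12.6 ± 1.80, the nuclear receptor Nr1d1 12.4 ± 2.97 and the clock output gene Dbp 11.03 ± 0.235, against 4.45 ± 2.96 for Clock and 2.70 ± 1.14 for Bhlhe41. The Nr1d1 peak lay on chromosome 11 at 98775241 to 98775480 in replicate 1. The median number of peaks in the gene body and 10 kb on each side was 7.5 and 4.5 for activity-regulated genes and 7 and 6 for clock genes, at percentiles of 99.95 and above.

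All 15 housekeeping genes had a promoter peak in both mice, at percentiles 98.6 and 99.7. Their median number of peaks was 5 and 4, at percentiles 99.645 and 99.35. The ribosomal genes Rplp0 at 10.4 ± 3.15 and Rpl13a at 9.10 ± 0.490 and the actin gene Actb at 8.72 ± 4.17 were highest, and Hprt at 2.42 ± 1.64 was lowest. Imprinted genes, expressed from 1 parental copy, had a peak at 13 and 12 of 17 promoters (73.5% ± 4.16), at percentiles 85.7 and 83.1. Kcnq1ot1 had 5.01 ± 2.02, Inpp5f 4.92 ± 0.183 and Peg3 4.67 ± 0.217. Airn (0.681) and Magel2 (0.581) had a peak in replicate 1 alone, Nnat (1.01) in replicate 2 alone, and H19 and Igf2 in neither. The parental copies were not told apart here.

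Hox genes, which pattern the body axis behind the forebrain, had almost no promoter peaks. A peak was present at 3 of 24 in replicate 1 and 1 of 24 in replicate 2 (8.33% ± 5.89), beside 83.7% and 75.8% for lists of like CpG content and length, and no matched random list was as low in either mouse. Hoxa7 had 1.65 ± 0.961, Hoxd13 (0.718) and Hoxa3 (0.231) had a peak in replicate 1 alone, and Hoxa10 was among those without. Midbrain and hindbrain genes had a peak at 7 of 11 promoters in replicate 1 and at 1 of 11 in replicate 2 (36.4% ± 38.6), at percentiles 6.03 and 0. Only Tph2, the serotonin-synthesis enzyme of the brain, had a peak in both mice (0.727 ± 0.0846). The serotonin transporter Slc6a4 (1.49), the homeobox genes En1 (1.36), En2 (0.931) and Barhl1 (0.525) and the paired box gene Pax2 (0.531) were among those with one in replicate 1 alone, and Gbx2 and Lmx1b had none. Striatal projection neuron genes had a peak at 5 and 4 of 6 promoters, at percentiles 59.2 and 31.1. Rgs9 had 3.83 ± 0.868 and the dopamine receptor Drd1 2.44 ± 0.176. Adora2a had a peak in replicate 1 alone (0.918), and the other dopamine receptor of the list, Drd2, had none. Choroid plexus and ependymal genes had a peak at 1 and 2 of 6 promoters, at percentiles 0.350 and 12.4. These were Foxj1, a transcription factor of ciliated cells, at 4.55 ± 0.208 and Kl in replicate 2 alone (0.922), with none at Aqp1 or Clic6.

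Promoters of liver, muscle, blood, epithelial and germ-line genes rarely had a peak. For liver it was 1 of 13 in each mouse (percentiles 0.865 and 2.06), the apolipoprotein gene Apob at 1.23 ± 0.675, with none at Alb or Ahsg. The Apob peak lay in an intron, 912 and 942 bp downstream of the nearest start site. For muscle it was 3 of 12 in each mouse (percentiles 10.5 and 18.5, or 1.28 and 2.96 by length alone). Ckm, the muscle creatine kinase, had 1.32 ± 0.396, and Myh7 had 0.872 ± 0.120 from different start sites. The Ckm peak lay in an intron, 805 and 800 bp downstream of the nearest start site. Tnnt2 had a peak in replicate 1 alone (0.581) and Tnni3 in replicate 2 alone (0.770), with none at Acta1 or Actc1. For blood it was 2 and 1 of 13 (percentiles 3.71 and 1.34, or 0.175 and 0.045 by length alone), with Pax5 at 0.871 ± 0.103, Tal1 in replicate 1 alone (0.993) and none at Cd3d. For epithelia it was 4 and 3 of 14 (percentiles 11.5 and 7.49, or 0.65 and 0.54 by length alone), with the podocyte gene Nphs1 at 1.56 ± 0.695, Cela1 at 1.45 ± 0.312, the stem cell gene Lgr5 at 1.08 ± 0.653 and Pdx1 in replicate 1 alone (0.406). Ins1 and Cdx2 had none. For the germ line it was 2 and 1 of 12 (percentiles 0.01 and 0.005), with Dazl at 2.00 ± 1.40, Pou5f1 in replicate 1 alone (0.662) and none at Ddx4 or Piwil1.

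**Figure D1:**
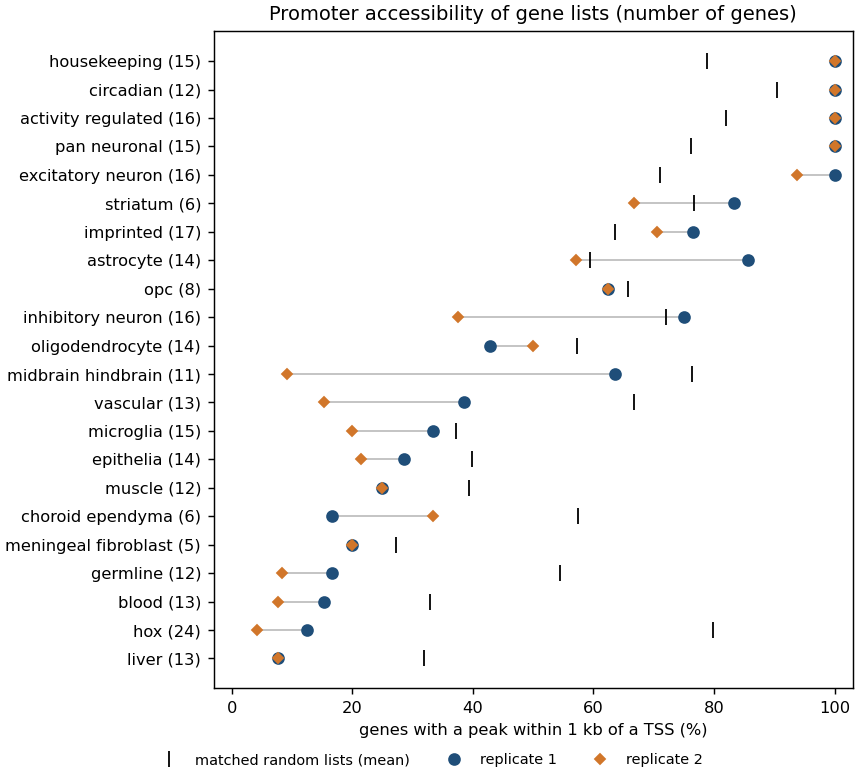
The share of each list's genes with a peak within 1 kb of a start site (x axis, percent) is drawn per list (number of genes in parentheses), with a circle for replicate 1, a diamond for replicate 2 and a tick for the mean of random lists matched on CpG content and gene length. Housekeeping, clock, activity-regulated and neuronal genes reach 100% in both mice, Hox genes lie at 12.5% and 4.17%, and the widest gap between the mice is that of midbrain and hindbrain genes, 63.6% and 9.09%.

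None of the 10 highest peaks of the genome lay at a gene of the fixed lists. No filter for multi-copy or hard-to-map sequence was applied to the peaks here. High signal at these 10 is therefore not shown to be high accessibility of a single locus. The first, on chromosome 17 at 39846781 to 39846920 (56.8 ± 30.8), overlapped Rn18s-rs5, annotated as a copy of ribosomal RNA sequence. The second was intergenic, on chromosome 3 at 5860361 to 5860530 (31.8 ± 13.9), with Gm8797 as its nearest coding gene, and the third lay in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase, on chromosome 9 at 123461881 to 123462140 (28.7 ± 14.8). The others of the highest 10 lay in an exon of Cers5 (24.1 ± 4.03), an intron of Il31ra (23.8 ± 10.8), near Igf2bp3 (22.5 ± 5.603), at the promoter of Hjurp (20.1 ± 6.56), at Gm15564 in Kpna1 (20.1 ± 5.20), at Gm23935 in Zc3h7a (18.9 ± 14.1) and at Gm21887 on chromosome X (17.2 ± 4.37). The genes with the most shared sites were long, and the counts were not scaled to gene length. Within the gene and 10 kb on each side, the ion channel gene Asic2 had 39, the transcription factor Camta1 36, the splicing factor Rbfox1 32, Csmd1 31, the synaptic scaffold Dlg2 30 and the synaptic adhesion gene Nrxn3 28, against a median of 2 per coding gene. The annotation gives Gm20388 (189 sites) a length of 4434882 bp, Fgfr2 (81) 2960900 bp and Gm37240 (30) 1391093 bp, and the number of shared sites rose with gene length across genes (Spearman rho 0.432).

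Promoters were the most enriched class of sites. Within 1 kb of a start site lay 36.7% ± 1.17 of the peaks (n = 2), 5.79 times the share of shuffled positions, while exons held 4.25% ± 1.04, introns 30.8% ± 0.0102 and intergenic sequence 28.2% ± 2.20. Shuffled positions fell at 6.34%, 3.40%, 40.2% and 50.1%. The median height was 1.964 and 1.47 at promoters, 1.04 and 0.949 in exons, 0.999 and 0.867 in introns and 0.943 and 0.812 between genes. Promoters made up 92.1% and 88.5% of the highest peaks in 10 equal groups by height and 18.9% and 20.6% of the lowest. All 4 classes differed from shuffled positions by more than the difference between the mice except exons in replicate 2, where the share was 3.51% against 3.38%.

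The X chromosome, present as a single copy in males, had fewer and lower peaks than the autosomes. It held 10.2 peaks per Mb in replicate 1 and 9.13 in replicate 2, against 29.4 and 24.1 on autosomes, which gives ratios of 0.348 and 0.379. The density of coding genes had a ratio of 0.669. The median peak height had a ratio of 0.689 and 0.652. At the X-linked gene Hprt, the promoter heights were 3.57 and 1.26.

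Over all peaks, matches of the insulator protein CTCF had the highest density relative to flanks among the 24 patterns. CTCF matches numbered 3709 in replicate 1 and 3834 in replicate 2, with a density 52.4 (95% interval 43.5 to 63.6) and 80.2 (64.6 to 100.8) times that of flanks 1 kb away, and 92.4% and 91.7% of them lay in the authors' footprints, short stretches protected from cutting, against 3 of 13 (23.1%) and 1 of 8 (12.5%) for the reversed pattern, which had few matches. The factor RFX had ratios of 22.8 and 46.8, ZNF143 36.4 and 58.6, ETS 10.2 and 15.3, the cAMP response element CRE 8.66 and 11.4, and the CCAAT box of NFY 3.54 and 4.68, with at most 1.76 for the reversed patterns of these. Reversal removes the CpG of the ETS and CRE patterns and adds CpG to the CTCF and NRF1 patterns. For all of these the control is not matched on CpG content. The EGR pattern keeps its CpG when reversed. NRF1 had 35.7 and 59.9, against 20.05 and 27.6 for its reversed pattern, and 83.4% and 82.6% of its matches lay in footprints, against 59.9% and 64.0% of the reversed ones. EGR had 30.04 and 23.3, against 29.2 and 23.3 reversed. The SP and KLF pattern had 10.7 and 12.5, and it reads the same in reverse, so it has no such control. Within 1 kb of a start site CTCF, at 15.8 and 26.2, lay below NRF1 (79.5 and 129.7, reversed 50.1 and 83.0), ZNF143 (44.3 and 158.8), EGR (48.4 and 29.98, reversed 50.05 and 29.5), RFX (31.4 and 57.3) and ETS (19.4 and 33.8), so EGR there was about as dense as its reversed pattern. ZNF143 and RFX rested on few matches there, 86 and 97 and 61 and 70 in peaks, so their order is uncertain. In replicate 1 alone, REST (26.3 and 5.73, from 17 and 7 matches) and the SP and KLF pattern (17.9 and 21.5) also lay above CTCF.

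At least 1 kb from a start site, the highest ratios were those of CTCF (83.3 and 114.6), RFX (19.8 and 44.0), EGR (9.62 and 10.4, reversed 7.35 and 9.23) and NRF1 (6.78 and 9.38, reversed 3.56 and 3.79). The NEUROD type of E-box had ratios of 3.14 and 3.70 there (2.14 and 2.57 in all peaks), AP1, a pattern of the Fos and Jun proteins, 2.79 and 3.48 (1.94 and 2.53), and MEF2 1.86 and 3.31 (1.27 and 2.33). Their reversed patterns had 0.910 and 0.965, 1.002 and 1.05, and 0.335 and 0.414 there. Among patterns of factors of other tissues, GATA had ratios of 0.429 and 0.387 over all peaks, against 0.563 and 0.698 reversed, and HNF4 0.516 and 0.487, against 0.542 and 0.520 reversed, so HNF4 was about as sparse as its reversed pattern. GRHL had 2.55 and 2.60 from 53 and 40 matches, against 0.656 and 0.692 reversed, where reversal also removes the CpG. HNF1 had 0 matches in peaks and only 3 and 1 in flanks, too few to compare. FOX had 0.510 and 0.590 (reversed 0.423 and 0.559), SOX 0.729 and 0.761 (0.769 and 0.703) and the T-box pattern 0.886 and 0.897 (0.947 and 1.01). ROR, at 0.837 and 1.13, POU, at 0.925 and 1.21, and PU1, a factor of microglia and other myeloid cells, at 1.31 and 1.45, lay above their reversed patterns, at 0.472 and 0.611, 0.338 and 0.354, and 1.03 and 0.942. NFI, at 2.84 and 5.54, and REST, at 10.9 and 4.10, rested on 33 and 41 and on 20 and 7 matches. The reversed NFI pattern, with 5 and 4 matches, had the higher ratios of 8.19 and 7.03. Reversal adds CpG to the POU and NFI patterns, so for them the control is not matched on CpG content.

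Single matches can be placed at named promoters. Their sequences are those of the GRCm38 reference, and differences of the B6CASTF1/J mice from it, or their effect on mapping, were not examined. The Camk2a peak held an RFX match, GTTACCGGGGCAAC, on chromosome 18 at 60925529 to 60925542, with 78.6% and 64.3% of its bases in footprints. The Rgs9 promoter held the CTCF match CCACCAGGGGGC on chromosome 11 at 109298259 to 109298270, and the Ckm promoter held CCACCAGATGGC on chromosome 7 at 19405553 to 19405564, both with 100% of their bases in footprints in each mouse. A CTCF match in the Gad1 peak, CCACCAGAGGGC on chromosome 2 at 70561199 to 70561210, had 0% in replicate 1, the mouse in which this promoter had a peak. The Gria2 promoter held the NRF1 match GCGCGTGCGC on chromosome 3 at 80802821 to 80802830, with 100% in both, and the Dlx6 promoter the CRE match TGACGTCA on chromosome 6 at 6862891 to 6862898, with 75% and 100%. Footprints numbered 288172 and 224558 (256365 ± 44982, n = 2), with a median width of 9 bp. Of these, 63.9% and 66.4% lay in peaks, and 28.4% (Wilson 95% interval 28.3 to 28.6) and 34.7% (34.5 to 34.9) were overlapped over at least 50% of their length in the other mouse. Inside peaks the shared percentages were 37.0 and 41.9, against 16.5 and 18.5 for footprints shuffled within peaks.

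**Figure D2:**
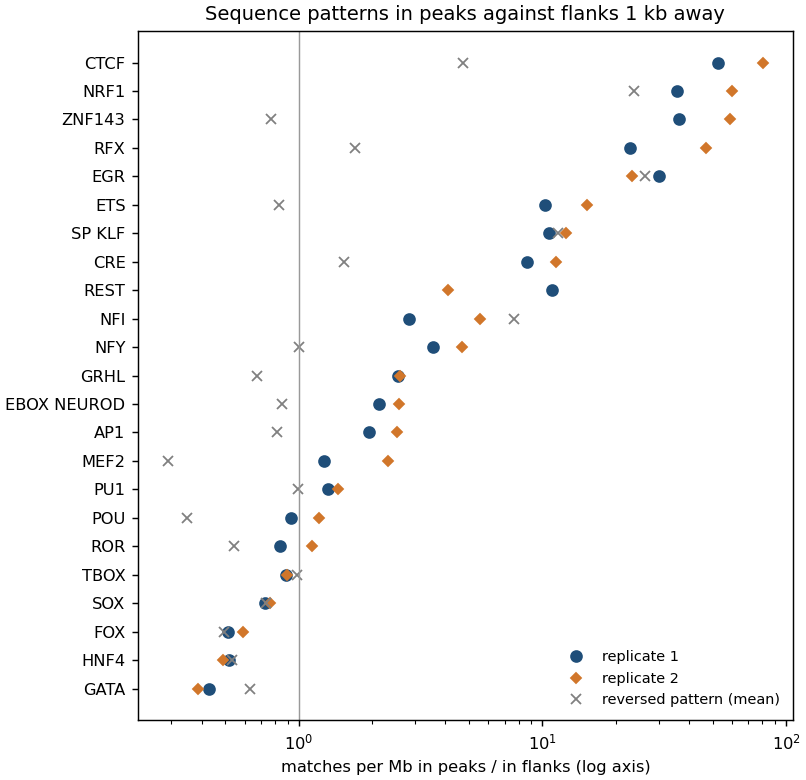
The density of matches in peaks divided by that in flanks 1 kb away (x axis, log scale) is drawn per sequence pattern, with circles for replicate 1, diamonds for replicate 2 and crosses for the mean of the reversed pattern. CTCF lies highest, at 52.4 and 80.2, the SP and KLF pattern reads the same in reverse, so its cross carries no information, REST has no reversed matches, and HNF1, with 0 matches, is left off.

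The highest peaks of each mouse nearly all overlapped a peak of the other, and the lowest often did not. Of the peaks of replicate 1, 45047 of 72021 overlapped a peak of replicate 2 (62.5%, Wilson 95% interval 62.2 to 62.9), and 45394 of 59150 peaks of replicate 2 overlapped a peak of replicate 1 (76.7%, 76.4 to 77.1), against 0.993% and 1.18% for shuffled positions. In 10 equal groups by height, the highest were shared at 99.1% and 99.5% and the lowest at 19.1% and 38.8%. Peaks found in 1 mouse alone had a median height of 0.774 and 0.626, against 1.66 and 1.16 for shared ones. Of the peaks found in 1 mouse alone, 43.7% and 49.6% overlapped the longer list of the other mouse, and 52.0% and 70.5% lay on bases that passed a false discovery rate of 0.05 in the other mouse, against 1.89% and 2.30% for shuffled positions. Heights at the 43755 shared sites correlated across sites with a Spearman rho of 0.825 and a Pearson r of 0.859 on the log2 scale. At promoters rho was 0.886, and elsewhere 0.744. Sites are not independent replicates, so no p is given.

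**Figure D3:**
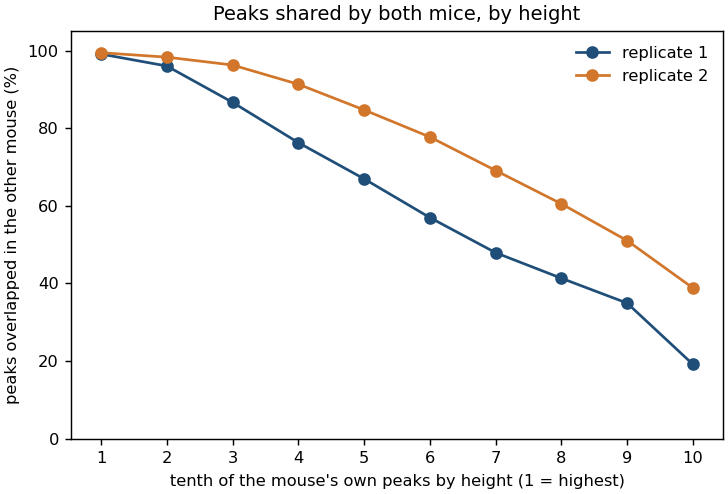
The share of peaks overlapped in the other mouse (y axis, percent) is drawn against height in 10 equal groups of each mouse's own peaks, from highest to lowest (x axis), with a line for each replicate. Sharing falls from 99.1% to 19.1% in replicate 1 and from 99.5% to 38.8% in replicate 2.

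Single sites and promoters differed in height between the mice. The largest ratios in favour of replicate 1 were at the promoter of Tmem64, on chromosome 4 at 15265901 to 15266280 (3.69 and 0.482, log2 ratio 2.94), an intron of Il1rapl1 on X (2.92), and the promoters of Ankrd52 (2.84), Zbtb10 (2.71) and Gabbr2, a GABA-B receptor subunit (2.58). In favour of replicate 2 the largest was intergenic, on chromosome X at 143482981 to 143483140, with Pak3 as the nearest coding gene (2.14 and 21.4, log2 ratio -3.32), followed by sites near Gm17332 (-2.46), at AU023762 (-2.20), near Cavin4 (-2.17) and at Gm10722 (-1.89), the last in sequence that is 100% repeat-masked. Over all shared sites the median log2 ratio of replicate 1 to replicate 2 was 0.46, with 79.4% of the sites higher in replicate 1. It was 0.72 at promoters, 0.31 elsewhere and 0.39 on X. After scaling to the median of shared sites these became 0.26, -0.15 and -0.07, since scaling sets the median of all shared sites to 0. The ratio rose with GC content, from 0.03 in the lowest of 10 equal groups of sites (mean GC 40.2%) to 1.17 in the highest (71.5%), with a Spearman rho of 0.508 across sites. Within 5 equal groups by GC, promoter and other sites differed by 0.02, -0.03, -0.01, 0.06 and 0.01, a comparison added after the data were seen. Sites found in replicate 2 alone made up 44.3% of the sites in the lowest GC group and 4.91% in the highest.

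**Figure D4:**
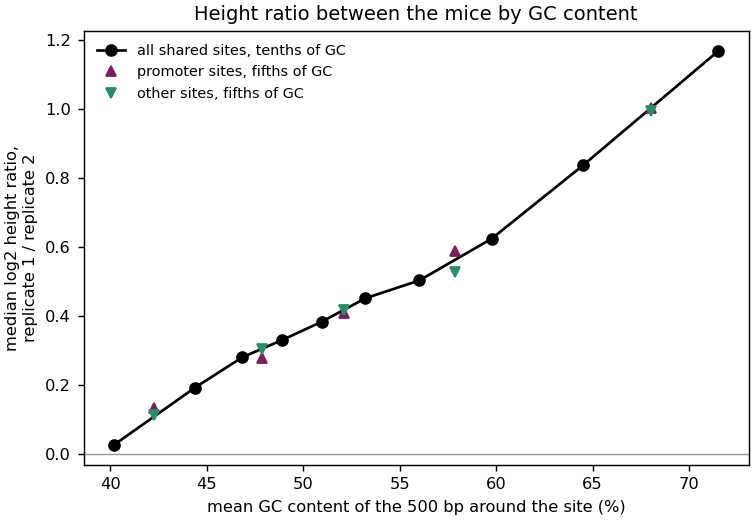
The median log2 height ratio of replicate 1 to replicate 2 at shared sites (y axis) is drawn against the mean GC content of the 500 bp around the site (x axis, percent), as a line for 10 equal groups of all sites and triangles for 5 equal groups of promoter and other sites. The line rises from 0.03 to 1.17, and the promoter and other triangles lie within 0.06 of each other.

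Gene lists differed between the mice in how many promoters had a peak and in the height of the highest promoter peak, which is not always the same peak in both, as at Slc1a2. The share was higher in replicate 1 by 37.5 points for inhibitory neuron genes (matched random lists 6.93, percentile 99.97), by 54.5 points for midbrain and hindbrain genes (7.97, percentile 99.995) and by 28.6 points for astrocyte genes (5.76, percentile 99.4). These 3 of 22 lists lay above the central 95% of random lists and 0 lay below it. A comparison chosen after seeing the data took promoters of like GC content and height with a peak in replicate 1. There the share lost in replicate 2 stood at percentile 83.2 for inhibitory neuron genes. For midbrain and hindbrain genes it was 98.7, or 92.1 with 1 fewer lost, and astrocyte genes were not compared in this way. Among promoters with a peak in both mice, compared with promoters of like GC content and height, 2 of the 8 lists with at least 5 such promoters lay outside the central 95% of random lists. Astrocyte genes had a median adjusted log2 ratio of -0.50 (percentile 0.56, higher in replicate 1 at 0 of 8) and imprinted genes -0.37 (1.46, 3 of 11). Before that adjustment both medians were positive, 0.19 with 6 of 8 higher in replicate 1 and 0.34 with 7 of 11, below the 0.72 of all promoter sites. The others were excitatory neuron genes at 0.03 (percentile 58.7), neuronal and synaptic genes at 0.00 (49.2), oligodendrocyte genes at -0.06 (39.5), clock genes at -0.10 (25.1), activity-regulated genes at 0.21 (94.7) and housekeeping genes at 0.27 (97.4). An alternative chosen after seeing the data kept the 92.0% of such promoters whose highest peaks overlapped, which left 7 lists with at least 5. Astrocyte genes then stood at -0.51 (percentile 1.11, 0 of 7) and housekeeping genes at 0.26 (97.7), both outside the central 95%, while imprinted genes at -0.36 (2.78, 2 of 9) fell inside it. Also inside were excitatory neuron genes at -0.08 (percentile 29.2), neuronal and synaptic genes at 0.00 (50.4), clock genes at -0.07 (29.2) and activity-regulated genes at 0.16 (85.3). With 1 library per mouse these percentiles are a description of these libraries, and none of these differences was tested across animals.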

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

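The tests of library depth, GC content, promoter position, GC content together with height, and signal under the threshold in each list apart were chosen after the results they address were seen, and those of promoter CpG content and of signal under the threshold in both lists together were set beforehand.

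The Y chromosome, outside the comparisons of the report, had 33 peaks in replicate 1 and 21 in replicate 2, of which 9 and 10 were shared, and drew attention because any count above 0 is signal in sequence not otherwise used. Peaks within 1 kb of a coding start site, 7 and 6, were at Eif2s3y (1.72 and 1.14 for the higher peak), Uty (1.76 and 1.81), Ddx3y (1.39 and 1.71) and Kdm5d (0.606 and 0.599), genes that are broadly expressed in males. The highest lay at 90744521 to 90744820 (5.44 and 3.61), 10150 bp from the start of Gm21860. These genes were named after their values were seen.

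Sites found in both mice, such as the promoters of Tmem64, Ankrd52 and Zbtb10, were mostly higher, after scaling to depth, in replicate 1. Library depth as the whole cause is argued against, since 1 factor would shift all sites alike, whereas the median log2 ratio of the sites with the highest GC exceeded that of the lowest by 1.14. Position at a promoter is argued against too, since promoter and other sites differed by 0.2 or more in 0 of 5 groups of equal GC content. A dependence of the libraries on GC content stays open and could account for the pattern, as the median ratio was 0.03 (0.0255) in the sites with the lowest GC and rose to 1.17 in the highest. No biological explanation was tested for this pattern or the next, since the labels name no difference between the mice other than their number.

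Promoters of inhibitory neuron genes such as Gad1, Gad2 and Lhx6, and of midbrain and hindbrain genes such as En1 and Slc6a4, had a peak more often in replicate 1. Promoter CpG content as the whole cause is argued against. Lists matched on it and on gene length differed by 6.93 and 7.97 points on average, against 37.5 and 54.5 here. The 2 lists were flagged for this same difference, so its percentiles (99.97 and 99.995) are no separate support. Astrocyte genes, at 28.6 against 5.76 points (percentile 99.4), were not followed up in this way. Against promoters of like GC content and height, the inhibitory list lost 8 of 12 in replicate 2 (66.7% against 53.6%, percentile 83.2), so these properties together could account for it, while midbrain and hindbrain genes lost 6 of 7 (85.7% against 45.0%, percentile 98.7), which stays open because 1 lost promoter fewer gives 92.1. Signal under the threshold in replicate 2 stays open as well, with listed bases at 9 of 14 promoters (64.3%, Wilson 95% interval 38.8 to 83.7). These were 7 of 8 inhibitory (87.5%, 52.9 to 97.8, or from 40.9 with 1 fewer) and 2 of 6 midbrain and hindbrain promoters (33.3%, 9.68 to 70.0). A promoter counted if any of its replicate 1 peaks met listed bases, as at En2 with 1 of 5 peaks and Dlx2 with 2 of 4. Of all promoter sites found in replicate 1 alone, 50.3% met such bases. That share counts single sites, so it is not a like measure to set beside the promoters. The demand that the interval exclude 50% and that 1 promoter fewer leave the call in place, and the reading of the lists apart from each other, were added after these values were seen, and without them the signal under the threshold would have counted for that explanation and the midbrain and hindbrain value against GC content and height.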

How the results depend on the processing

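Some alternatives were chosen after seeing the data. They were those for the height ratio of promoter to distal peaks, with the other peak list and among shared peaks. The promoter minus distal log2 ratio over groups of equal GC content was another. The others of this section were chosen beforehand. No paired analysis was possible because the series has only 1 group. Footprints could not be split by score, which is constant. The effect of depth on the calls was not tested. Of 48 values of the main results under alternatives, 9 moved by less than the spread between the mice or their interval, 38 moved further and 1 changed sign. Changes of numbers with the set of peaks, the window or the overlap follow from construction, and for the rest the cause was not tested.

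With the other peak list, the number of peaks per mouse was 114480 and the covered length, Mb, was 23.5. With the higher 50% of the peaks by height, the number of peaks per mouse was 32897.5, the median peak width, bp, 230 and the covered length, Mb, 8.19. The percent of the peaks of replicate 1 shared was 48.8 with an overlap of at least 50% of both peaks, 70.5 with equal numbers, 68.8 with the higher peaks and 59.6 with the other list. The percent of the peaks of replicate 2 shared was 59.3, 71.2, 83.1 and 72.6 under these settings. The Spearman rho of heights across shared sites was 0.846 and the Pearson r of log2 heights across shared sites 0.868 with reciprocal overlap, and 0.744 and 0.777 without promoter peaks.

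The percent of peaks at promoters was 30.5 within 500 bp, 45.0 within 2500 bp, 33.0 for protein-coding genes only and 50.2 for the higher peaks. The percent of cortical cell-type genes with a promoter peak was 45.5 for the higher peaks. The percent of genes of other tissues and germ line with a promoter peak was 10.9 within 500 bp, 26.6 within 2500 bp and 7.81 for the higher peaks. The ratio of X to autosomes, peaks per Mb, was 0.296 for distal peaks. The ratio of X to autosomes, median peak height, was 0.628 for distal and 0.702 for shared peaks. The ratio of promoter to distal median peak height was 2.16 for shared peaks.

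The percent of the footprints of replicate 1 shared was 34.3, and the percent of the footprints of replicate 2 shared 43.2, with overlap by 1 bp. The ratio of matches in peaks to flanks, CTCF, was 99.0 in distal peaks. The percent of matches in footprints, CTCF, was 92.6 in distal and 93.7 in shared peaks. The median log2 height ratio of replicate 1 to replicate 2, promoter sites, was 0.72 without scaling. The median log2 height ratio of replicate 1 to replicate 2, distal sites, was 0.31 without scaling, against -0.15 with it, and changed sign because scaling subtracts the median of all shared sites. The promoter minus distal median log2 height ratio was 0.0103 over 5 groups of equal GC content, against 0.40. The percent of the peaks of replicate 1 absent from the other mouse was 21.1, and the percent of the peaks of replicate 2 absent from the other mouse 11.7, when both lists were asked.

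Leaving out each mouse gives the value of the other, so with 2 mice these 24 values always lie within 1 SD of the mean by construction. The number of peaks per mouse ranged from 59150 to 72021, the median peak width, bp, from 200 to 205, the covered length, Mb, from 11.2 to 16.0 and the percent of peaks at promoters from 35.9 to 37.6. The percent of cortical cell-type genes with a promoter peak ranged from 55.0 to 68.5, and the percent of genes of other tissues and germ line with a promoter peak from 14.1 to 18.8. The ratio of X to autosomes, peaks per Mb, ranged from 0.348 to 0.379, the ratio of X to autosomes, median peak height, from 0.652 to 0.689 and the ratio of promoter to distal median peak height from 1.72 to 2.00. The number of footprints per mouse ranged from 224558 to 288172, the ratio of matches in peaks to flanks, CTCF, from 52.4 to 80.2 and the percent of matches in footprints, CTCF, from 91.7 to 92.4.

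Among the percentiles of the 22 lists, matching on gene length alone kept 32 of 44 on the same side of the central 95%, brought in 2 (inhibitory neuron, replicate 2; astrocyte, replicate 1) and took out 10 (microglia, clock and epithelia in both mice; meningeal, activity, muscle and blood in replicate 1). Of 405 promoter heights of named genes 22 moved by more than the spread, as did 24 of 66 list shares, 35 of 44 list peak numbers, 26 of 46 pattern ratios and 15 of 44 shares of matches in footprints.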

Other observations

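The tests of clock phase and neuronal activity were set before their results were seen, but the way they are read was made stricter afterwards, and the families below were chosen after their values were seen.

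Families of genes taken by name, some with members in the fixed lists, differed widely in promoter accessibility. Genes named Nduf, mostly of respiratory complex I, had a promoter peak at 97.8% of 46 in both mice, the proteasome at 94% of 50, and genes named Rpl or Rps, mostly ribosomal proteins, at 89.8% of 98. Zinc finger genes named Zfp had 86.3% and 83.2% of 394, and histone genes 86.6% and 85.1% of 67. Clustered protocadherins, which give single neurons their surface identity, had 12.5% and 8.93% of 56, keratins 11.3% and 9.43% of 53, cytochromes of the Cyp2 family 16.3% and 14.3% of 49, and beta-defensins 2.38% and 7.14% of 42.

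Families of channels and receptors had a promoter peak more often in replicate 1. Glutamate receptor subunits had one at 89.5% in replicate 1 and 73.7% in replicate 2 of 19 genes, GABA-A receptor subunits at 68.4% and 42.1% of 19, and potassium channels at 76.6% and 61.7% of 94. The median promoter heights were 2.70 and 1.56, 2.45 and 1.25, and 2.25 and 1.29. Whether these differences exceed those of other genes of like GC content was not tested.

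A difference in clock phase between the mice was put as a hypothesis, because clock genes change over the day. Per1 (11.4 and 13.9) and Nr1d1 (14.5 and 10.3) differed in opposite directions. The median adjusted log2 ratio of the 12 clock promoters was -0.10, at percentile 25.1, inside the range of random lists, which as first set would have counted against the hypothesis. That reading was not kept, because clock genes peak at different times and opposite moves cancel in a median (4 of 12 were higher in replicate 1 after adjustment for GC content and height, and 9 of 12 before), so a phase difference cannot be told from none here. A difference in neuronal activity, read from the 16 activity-regulated promoters, gave 0.21 at percentile 94.7, with 12 of 16 higher in replicate 1 after adjustment and 16 of 16 before. The value lies inside the range of random lists, -0.27 to 0.25, as does the 0.16 (percentile 85.3, 8 of 13 higher) of promoters whose highest peaks overlap, an alternative chosen after seeing the data. As first set the test would have counted against the hypothesis, but these promoters too moved in both directions after adjustment, so it stays open.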
